A study of Oryza sativa with 4 samples.

How the data were processed

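Small RNA was sequenced from leaf and root of the salt-tolerant rice cultivar Pokkali, without salt and after 200 mM NaCl for a time the labels do not give. There was 1 library in each of the 4 groups. Per the labels' protocols, RNA was extracted with Trizol, enriched for small RNA, selected on a gel at 15 to 30 nt and built into Illumina TruSeq libraries. The deposited files hold read counts: each line gives a distinct sequence and the raw count of reads with that sequence, with no normalization. The trimming, filters, aligner and genome build are not given in the sources used here. Adapter trimming and length filters act before these counts, and the longest sequence held was 25 nt in leaf control, 28 nt in leaf salt and 42 nt in both root libraries. The series text speaks of different varieties, while every sample is labelled Pokkali.

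Counts were scaled to reads-per-million values (RPM) over the reads of 18 to 30 nt in each library. A read of 18 to 24 nt was assigned to a microRNA family when its first 18 nt (16 nt for tasiR-ARF) equalled those of a listed mature sequence. The list held 80 sequences of 39 rice families, and was written from general knowledge before the data were examined. No genome was used here, so family names rest on sequence matches alone, no locus or hairpin was checked, and the planned sorting of reads into ribosomal, transfer and organelle classes was not run. Identical mature sequences from different loci cannot be told from each other and were summed per family. The listed sequences of miR1318 and miR1432 are the same RNA read 1 base apart, so these names do not stand for independent measurements. The families were grouped into 8 lists by target, response or taxonomic range, also fixed before the data were examined; a family can stand in more than a single list, as miR528 does.

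A family entered a comparison with at least 30 reads and at least 10 RPM in 1 of its libraries, and was called higher or lower at a ratio of at least 2 or at most 0.5. Ratios carry exact conditional binomial (Clopper-Pearson) 95% intervals, and shares carry exact binomial 95% intervals. All intervals and floors cover counting error only: reads are not independent molecules, and with 1 library per group no difference has a replicate check, a test or a p-value. A library with 0 reads was set at a floor of 3 reads to give a bound; the exact interval of such a ratio starts lower. The log2 ratios had 0.5 read added to each count. The interval of the difference between tissues used a normal approximation. The median of each list was placed among 10000 random lists of the same size, drawn from single sequences of 20 to 24 nt with at least 30 reads in 1 of the libraries and a mean abundance within 0.5 on the log2 scale of the member's, or from the nearest 100 where fewer were. Families sum several sequences and the random lists do not, so a percentile describes these libraries and is no test. A first version that always drew from the nearest 100 gave percentiles off centre for simulated lists with no effect, since many sequences share a mean, and was replaced before the percentiles of the real lists were read. With the band, simulated lists with no effect had a median percentile of 53.5 for the leaf pair, 51.0 for the root pair, 45.4 for root control against leaf control and 46.4 for root salt against leaf salt. With 6 added to the median log2 ratio, 100% of simulated lists lay below percentile 5 or above 95 in the leaf and root pairs. The share was 98.5% for root control against leaf control and 71% for root salt against leaf salt. A middle percentile thus does not show that a list was unshifted.

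Named families were, per comparison, up to 12 with the highest and up to 12 with the lowest called ratio, and the 2 most abundant members of each list. Control sequences of animals and dicots are given as counts. Of the 5 most abundant unlisted sequences of each library, 2 examples are given by length and count, chosen after their values were seen. Families outside this rule that are named were chosen after their values were seen.

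The steps were checked on simulated data. Of 546 simulated reads made from listed sequences 544 went to their family, and the exceptions were miR1318 and miR1432 under the shifted-start rule. None of 200000 random sequences was assigned. For leaf salt against leaf control, with 22 families, 96.5% of intervals covered a simulated ratio of 1, and for root salt against root control, with 31 families, 95.0% did. In both, 0% of families simulated at a ratio of 1 and 100% of those at 4-fold were called. A simulated ratio of exactly 2 was called in 55.5% of draws for the leaf pair and 46.6% for the root pair, so counting error decides calls next to the threshold. The simulations hold counting error alone. Their rates were pooled over both libraries of a pair, and families with under 30 expected reads in the control library were left out. Low control counts were thus not simulated: miR1318, with 2 reads in leaf control, entered at a higher count. The rates of 0% and 100% do not cover such families.

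The alternatives were other scales (reads of 20 to 24 nt, reads of listed families, median-of-ratios size factors), exact full-length matches, 1 mismatch, other read minimums and a whole interval beyond 2-fold. Scaling to 18 to 25 nt reads, shifted starts, a first-15-nt match, thinning to the depth of leaf control and the grass or rice restricted list without miR530 were alternatives chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.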

Results

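Small RNA of Pokkali rice was profiled in leaf control, leaf salt, root control and root salt plants, with 1 library each. The files held 2253207 reads for leaf control, 18653772 for leaf salt, 24125165 for root control and 54220955 for root salt. Reads of 18 to 30 nt numbered 2240583, 18237453, 14584896 and 30794518, a 13.7-fold range. A single read was worth 0.446 RPM in leaf control and 0.0325 in root salt, so low families were measured least precisely in leaf control.

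By reads, lengths of 21 and 24 nt, the usual sizes of plant microRNAs and of heterochromatic small interfering RNAs, led in all 4 libraries. The 24 nt share was 42.5% (95% interval 42.4 to 42.5) in leaf control and 34.7% in leaf salt, against 32.8% in root control and 33.8% in root salt, all with narrower intervals. The 21 nt share was 26.2% in leaf control, 28.8% in leaf salt, 20.8% in root control and 19.2% in root salt. Leaf control held no reads beyond 25 nt and leaf salt none beyond 28 nt, so these shares have unlike bases. Reads of 18 to 25 nt numbered 2240583 in leaf control, 17411775 in leaf salt, 12119696 in root control and 26631810 in root salt. Over those reads the 24 nt share was lowest in leaf salt, and the 21 nt shares of leaf control and root control lay closer. Without the 10 most abundant sequences the 21 nt share was 8.78% in leaf control, 14.5% in leaf salt, 7.26% in root control and 8.16% in root salt, and the 24 nt share of leaf control was then 68.2%. Among distinct sequences 23 nt outnumbered 21 nt in every library, with 12.8% against 5.75% in leaf control. Among 21 nt reads, 89.3% in leaf control began with U, and among 24 nt reads 63.3% began with A; in leaf salt these shares were 80.1% and 42.2%. The 10 most abundant sequences held 37.5% of leaf control reads, 28.2% of leaf salt, 16.6% of root control and 14.1% of root salt. Reads outside 18 to 30 nt made up 0.560% of leaf control and 43.2% of root salt.

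**Figure D1:**
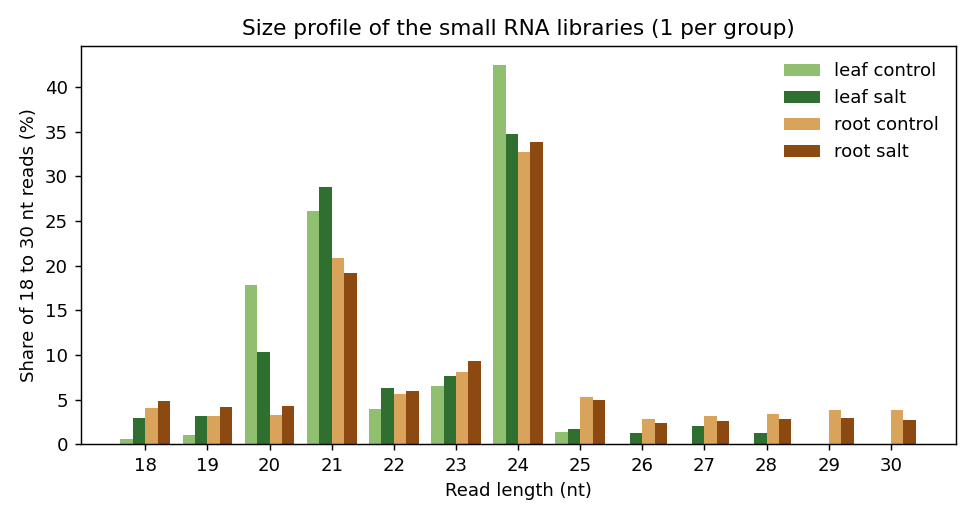
Share of 18 to 30 nt reads (%, y axis) at each read length in nt (x axis), with 1 bar per library. The 24 nt bar of leaf control reaches 42.5% and those of the other libraries lie between 32.8% and 34.7%; leaf control has no reads beyond 25 nt.

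Listed families held 19.9% of the 18 to 30 nt reads in leaf control, 20.6% in leaf salt, 12.9% in root control and 10.3% in root salt. miR156, which targets SPL transcription factors, made up 82.2% of family reads in leaf control. miR168, which targets the slicer ARGONAUTE1, made up 49.4% in leaf salt. miR166, which targets HD-ZIP III factors, made up 80.9% in root control and 75.5% in root salt. These shares count reads at the listed starts only. With shifted starts, listed families held 38.8% in leaf control, 30.4% in leaf salt, 16.9% in root control and 14.3% in root salt. In leaf salt miR156 then led, with 2858852 reads against 1948598 for miR168. miR2275, known from reproductive tissue, had 0 reads in every library, which allows up to 1.34 RPM in leaf control by the floor of 3 reads and 1.65 by the exact interval.

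The series title names salt tolerance in Pokkali, and the first comparison set leaf salt against leaf control. Of 4 families linked to copper supply and oxidases, the 3 that passed the minimum were lower in the salt library. miR408, which targets blue copper proteins, stood at 0.439 RPM against 30.8, a ratio of 0.0142 (95% interval 0.00591 to 0.0297) from 8 and 69 reads, or 0.0257 with shifted starts. miR397, which targets laccases, had a ratio of 0.0678 (0.0476 to 0.0958), and miR528, a monocot family, stood at 612 RPM against 5067, a ratio of 0.121 (0.118 to 0.124). All were at least 2-fold lower, and their median log2 ratio of -3.88 lay at percentile 1.61 of random lists. miR398, below the minimum, had 31 reads against 1, a ratio of 3.81 (0.635 to 155). Most miR397 reads began 3 bases downstream of the listed start and were not in this count; that form was also lower, at 64.9 against 1997 RPM.

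Of 28 families that passed the minimum in leaf, 14 were at least 2-fold higher and 7 at least 2-fold lower with salt. miR820, which targets a DNA methyltransferase, was 24.3-fold higher (19.3 to 31.2), at 771 against 31.7 RPM, though its exact full-length matches numbered 212 and 0. A 24 nt form that extends the listed sequence held 12083 and 63 of its reads. miR1425 was 18.9-fold higher (12.4 to 30.2). miR1318 was 33.5-fold higher, with an interval of 9.24 to 278 that reflects 2 reads in leaf control, and miR1432, the same RNA read 1 base apart, was 4.60-fold higher. With exact matches miR1432 kept 104 and 4 reads, a ratio of 3.19, and fell below the minimum. miR530 had 0 reads in leaf control and 686 in leaf salt, at least 28.1-fold higher against a floor of 3 reads (exact interval from 22.8), but 6 of the 686 were exact full-length matches, too few for a call. Of the 8 measured grass or rice restricted families, 6 were higher and 1, miR528, lower, though miR1318 and miR1432 are not independent members and miR1861, at 2.13, had a ratio of 1.59 with median-of-ratios scaling. Their median log2 ratio of 3.19 lay at percentile 92.2. Without miR530, which dicots also have, 5 of 7 were higher and 1 lower, and the median of 2.17 lay at percentile 77.6. Below the minimum, miR1850 of this list had 13 reads against 26, a ratio of 0.0614 (0.0290 to 0.124), and miR1876 had 91 against 0.

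Among the 9 measured developmental families in leaf, 5 were higher and 2 lower, with a median log2 ratio of 1.53 at percentile 64.1. miR156 was lower, at 68583 against 163565 RPM, a ratio of 0.419 (0.418 to 0.421). miR172, which targets AP2 factors, was 3.17-fold higher (2.92 to 3.44). miR166 was 5.06-fold higher, miR535 was 5.08-fold higher, and miR164 had a ratio of 0.289 (0.260 to 0.321). miR159, which targets MYB factors, was 9.11-fold higher (8.08 to 10.3), but 108 of its 20168 reads in leaf salt were exact full-length matches, and with such reads alone the log2 ratio was -2.89. Matched by the first 15 nt, which takes in a 17 nt form, miR159 had 176352 and 350 reads, a ratio of 61.9. miR396 and miR444 had ratios of 1.48 and 1.20, and miR444 turned to a log2 ratio of -0.15 with median-of-ratios scaling. The miR396 sum hid opposite members by exact matches. miR396c stood at 16.0 RPM in leaf salt against 139.7 in leaf control, and miR396d at 1821 against 1156.

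In the list of families that target small RNA pathway genes or a DNA methyltransferase, miR168 was 5.18-fold higher in leaf salt (5.13 to 5.23), at 101791 against 19643 RPM, and the list had 2 of 3 members higher with a median at percentile 69.5. Its other member, miR162, had a ratio of 0.514 (0.424 to 0.627), which became a lower call with listed-family scaling (0.496) and median-of-ratios scaling (0.384). Auxin-linked families went both ways: miR167 was 3.47-fold higher, or 5.70-fold with exact matches, while miR390 had a ratio of 0.156 (0.101 to 0.241), and the list median log2 ratio was 0.43 at percentile 59.2. tasiR-ARF, with 0 exact matches to the listed sequence in any library, had a ratio of 0.450 (0.327 to 0.628) from 183 and 50 reads, but 0.885 with 1 mismatch allowed and 0.722 with shifted starts, so its call was lost. Of the 4 families tied to salt or osmotic stress in earlier plant work, miR169 was 3.41-fold higher (2.52 to 4.71), the others lay within 2-fold, and the median log2 ratio of 0.50 lay at percentile 51.4. In the phosphate and sulfate list only miR827 passed the minimum, with a ratio of 1.18 (0.992 to 1.42) and percentile 33.8, and its log2 ratio became -0.18 with median-of-ratios scaling. miR399 of this list, below the minimum with 137 reads against 1, had a ratio of 16.8 (2.97 to 670). Median-of-ratios scaling moved the median log2 ratio of all leaf families by -0.42. Leaf control was the shallowest library and held 137 reads of animal control sequences, 61.1 RPM, against 0.110 RPM in leaf salt, and leaf salt has no other control library.

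**Figure D2:**
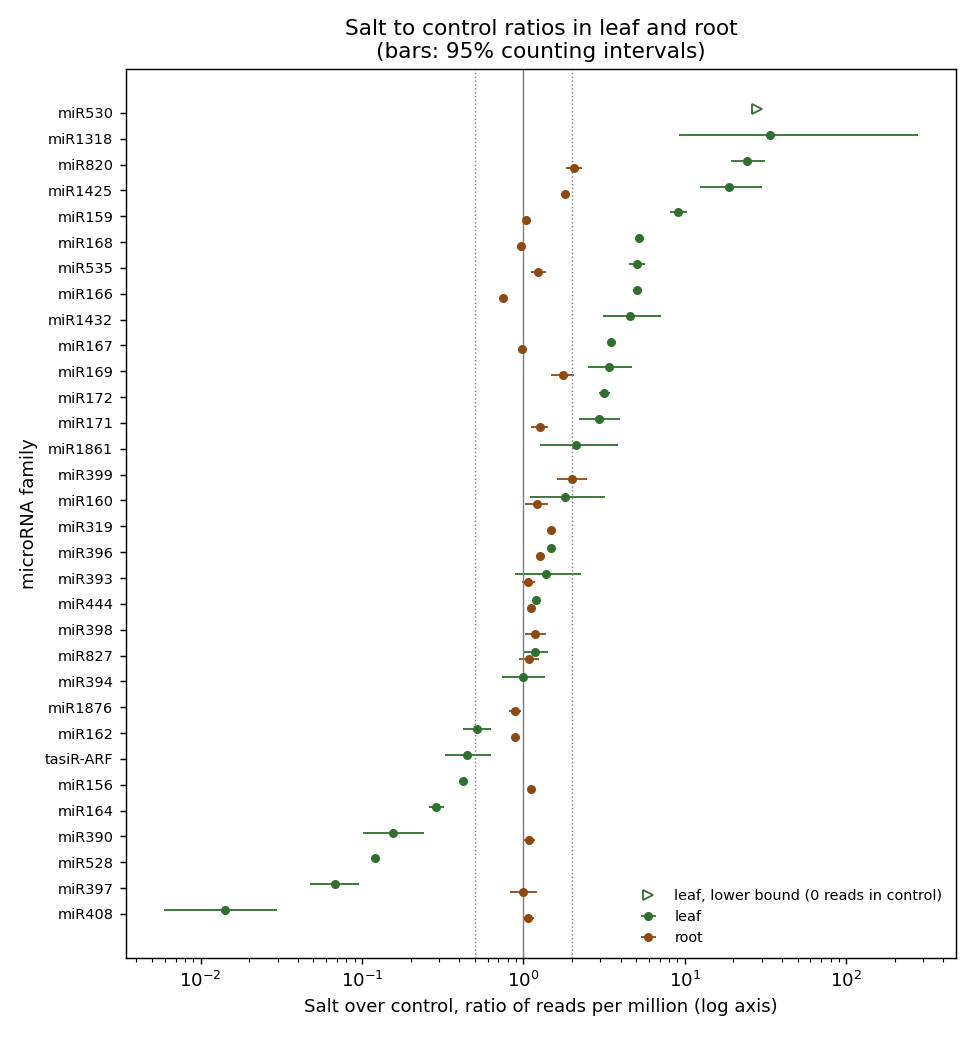
Ratio of RPM, salt over control (log x axis), for each microRNA family (y axis) in leaf and root, with 95% counting intervals; dotted lines mark ratios of 0.5 and 2, and the open arrow is a lower bound. Leaf ratios run from 0.0142 for miR408 to 33.5 for miR1318, and root ratios from 0.749 to 2.06.

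Root salt was then set against root control. Ratios were close to 1: of 23 families that passed the minimum, 1 was at least 2-fold higher and 0 at least 2-fold lower, and 19 lay within 1.5-fold. The family called was miR820, at 48.5 against 23.6 RPM, a ratio of 2.06 (1.83 to 2.32). The interval reaches below 2, and with median-of-ratios scaling its log2 ratio was 0.93, below the threshold; 33 and 6 of its reads were exact full-length matches, too few for a call. miR399, which targets a phosphate regulator, had a ratio of 1.99 (1.61 to 2.49), and miR1425 had 1.81 (1.76 to 1.87); scaled by listed-family reads they had 2.49 and 2.26. The most abundant family, miR166, stood at 77917 against 104035 RPM, a ratio of 0.749 (0.747 to 0.750).

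By list, the 3 measured copper and oxidase families of root were within 2-fold, with a median log2 ratio of 0.10 at percentile 61.3; miR408 had a ratio of 1.07 (0.988 to 1.17) and miR398 1.19 (1.02 to 1.38). The 8 developmental families were within 2-fold, with a median of 0.23 at percentile 74.1 and a miR156 ratio of 1.11 (1.10 to 1.13). The 4 auxin-linked families had a median of 0.11 at percentile 56.5, and miR390 and miR167 had ratios of 1.08 and 0.986. The 3 stress-linked families had a median of 0.33 at percentile 76.7, and miR396 and miR393 had ratios of 1.26 and 1.07. The phosphate families had a median of 0.55 at percentile 86.2, with miR827 at 1.08. The 4 grass or rice restricted families, of which miR820 was higher, had a median of 0.51 at percentile 86.3, with miR444 at 1.12. In the small RNA pathway list, which also holds miR820, the median was -0.06 at percentile 32.4, with miR168 at 0.960 and miR162 at 0.882. The sign of the log2 ratio depended on the scale for 9 of the 23 families, among them miR162, miR167, miR168, miR393, miR408 and miR827, none of which was called. Scaling by listed-family reads moved the median log2 ratio by 0.32, and median-of-ratios scaling by -0.11.

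Root control was set against leaf control to compare the tissues without salt. Animal control sequences stood at 61.1 RPM in leaf control and 1.30 in root control, and dicot ones at 10.7 and 0. The 5' adapter share was 0.814% in leaf control and 0.0554% in root control. Tissue cannot be told apart from such differences between the libraries. miR166 was 65.6-fold higher in root (63.5 to 67.8), at 104035 against 1586 RPM. By exact matches its main member miR166a stood at 103266 against 1080 RPM, and miR166e and miR166m were also higher in root. miR166g and miR166k went the other way, at 34.7 against 217.8 RPM and 11.7 against 181.6. miR319, which targets TCP factors, had 9865 reads in root and 0 in leaf control, at least 505-fold higher against a floor of 3 reads (exact interval from 411), and miR1876 was at least 42.04-fold higher (from 34.1). Of the miR319 reads 713 were exact full-length matches, and 8195 were the listed sequence with 1 more base. A 22 nt form 1 base upstream, not in this count, had 34892 reads in root control and 0 in leaf control. miR1425 was 36.0-fold higher (23.8 to 57.5), miR159 7.30-fold and miR162, which targets a Dicer gene, 5.36-fold. Lower in root were miR528 at a ratio of 0.00175 (0.00146 to 0.00208), miR172 at 0.00229 (0.00104 to 0.00438), miR156 at 0.0155 and miR164 at 0.0214. With exact matches miR159 was 13.0-fold and miR393 2.39-fold higher in root. Of 27 families 10 were at least 2-fold higher and 10 at least 2-fold lower.

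In that pair the developmental list had 3 members higher and 4 lower of 10, with a median log2 ratio of -0.32 at percentile 24.06. Among 5 auxin-linked families miR393 was 5.01-fold, miR390 3.26-fold and miR160 2.05-fold (1.23 to 3.64; 1.94 in thinned libraries) higher in root, and the median of 0.99 lay at percentile 52.1. miR167 had a ratio of 0.154, but 0.918 with exact matches, from 4937 and 826 reads. That sum hid opposite members: miR167a stood at 4.73 RPM in root control against 291.4 in leaf control, and miR167d at 333.8 against 77.2. A 22 nt form of miR167, no exact match, stood at 488 against 5162 RPM. tasiR-ARF had a ratio of 0.0768 from 25 and 50 reads, none an exact match; with shifted starts it stood at 53.5 against 231 RPM. Of 4 copper and oxidase families 1 was higher and 2 were lower, and the median of -0.52 lay at percentile 38.3. miR398 had a ratio of 36.7 with an interval of 6.53 to 1456 from 1 read in leaf control (12.5 with shifted starts). The miR397 ratio was 0.264. miR408, at 1.85, was beyond 2-fold on every other scale tried. Its ratio ran from 2.22 with reads of 18 to 25 nt to 2.86 with listed-family reads, and was 2.55 with median-of-ratios scaling. miR394 and miR827 had ratios of 0.216 and 0.308. The stress-linked list, with 1 of 4 higher and 1 lower, lay at percentile 44.4, and the small RNA pathway list, with 1 of 3 higher, at 40.3. The grass or rice restricted list, with 2 of 5 higher and 1 lower, lay at 37.8, and the phosphate list, by miR827 alone, at 44.7; its member miR399, below the minimum, had 105 reads against 1, a ratio of 16.1 (2.83 to 643). miR168 and miR396 had log2 ratios of -0.23 and -0.18 that turned to 0.23 and 0.28 with median-of-ratios scaling and were above 0 with every other scale tried, and miR444, at -0.46, turned to 0.16 when scaled by listed-family reads. By exact matches the miR444 sum hid opposite members. miR444b.1 stood at 210.8 RPM in root control against 15.6 in leaf control, and miR444b.2 at 219.3 against 549.4. Median-of-ratios scaling moved the median log2 ratio by 0.46.

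Root salt was set against leaf salt, a comparison that does not use leaf control. Of 32 families 10 were at least 2-fold higher and 17 at least 2-fold lower in root. With median-of-ratios scaling, which moved the median log2 ratio by 1.27, and with listed-family scaling, which moved it by 1.00, the split was 12 and 12, and miR169, miR171, miR394, miR827 and miR1861 were no longer called lower. miR319 was 1670-fold higher in root (933 to 3345), miR408 139-fold (70.5 to 323), miR390 22.7-fold (17.2 to 30.5), miR398 11.4-fold and miR166 9.71-fold (9.66 to 9.77). By exact matches miR166a stood at 77224 against 3846 RPM, and miR166e was also higher in root. miR166g and miR166k went the other way, at 25.1 against 1916 RPM and 11.5 against 1226, as did miR166i and miR166m. miR172 had a ratio of 0.000381 (0.000183 to 0.000701), miR528 0.0134 and miR156 0.0412, and miR530 had 0 reads in root salt against 686 in leaf salt, at least 386-fold lower against the floor (exact interval from 313), though 6 of the 686 were exact full-length matches, too few for a call. With exact matches miR319 was 307-fold higher and miR167 had a ratio of 0.183, and with shifted starts miR408 was 73.9-fold higher. miR168 was lower in root at 0.157 and miR820 at 0.0629.

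By list, 3 of 4 copper and oxidase families were higher in root salt, with a median log2 ratio of 2.72 at percentile 65.4. The developmental list had 2 higher and 5 lower of 10, at percentile 35.8. Among the lower was miR171, whose log2 ratio of -1.03 turned to 0.23 with median-of-ratios scaling. With shifted starts the miR171 ratio was 2.27, past 2-fold the other way. miR159 of this list, not called at 0.830, had a ratio of 98.5 with exact matches, from 17969 and 108 reads. Matched by the first 15 nt it had 0.0993. Below the minimum, miR529 of this list had 227 reads in root against 7, and miR1850 of the grass or rice list 183 against 13, ratios of 19.2 (9.17 to 48.3) and 8.34 (4.76 to 16.0). Auxin-linked families had 2 higher and 2 lower of 5, at percentile 52.4, with miR393 3.90-fold higher, or 1.84-fold with exact matches, and miR167 at a ratio of 0.0438. The grass or rice restricted list had 2 higher and 6 lower of 9 at percentile 32.3, or 2 and 5 of 8 at 32.2 without miR530. The stress-linked list had 1 higher and 2 lower at percentile 43.6, the small RNA pathway list 1 higher and 2 lower at percentile 35.1 and the phosphate list 0 higher and 1 lower at percentile 48.8. In the phosphate list miR399, at 1.91 (1.57 to 2.33), was beyond 2-fold on every other scale, from 2.11 with reads of 18 to 25 nt to 4.60 with median-of-ratios factors, and at 2.44 with exact matches. miR827 was at 0.675 with median-of-ratios factors, so that scaling gave 1 higher and 0 lower. miR396 and miR444 had log2 ratios of -0.41 and -0.57, which turned to 0.86 and 0.69 with median-of-ratios scaling. By exact matches the miR444 sum hid opposite members. miR444b.1 stood at 217.7 RPM in root salt against 34.8 in leaf salt, and miR444b.2 at 260.7 against 628.8.

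Of the 27 families measured in both root to leaf comparisons, 8 were higher in root in each, against 3.70 for independent lists of 10 and 10 families. They were miR162, miR166, miR319, miR390, miR393, miR398, miR1425 and miR1876. In each, 9 were lower in root, against 4.81 for independent lists of 10 and 13 families: miR156, miR164, miR167, miR172, miR394, miR528, miR535, miR827 and tasiR-ARF. In a comparison each, the calls of miR167 and miR393 were lost with exact matches and those of miR394 and miR827 with median-of-ratios scaling. For miR167, without salt, the exact matches summed members that went opposite ways. With salt, tasiR-ARF fell below the minimum in thinned libraries, with 1 and 27 reads. The root to leaf comparisons share no library, but both set the same tissues against each other. Independence is thus a weak baseline, and the overlap is no test. miR397 was the 1 family with opposite calls, at a ratio of 0.264 without salt and 3.89 (2.91 to 5.30) with salt. With salt, miR397 had ratios of 3.13 with exact matches (275 and 52 reads) and 3 in thinned libraries (18 and 6 reads), below the minimum for a call, and stood at 724 against 127 RPM with shifted starts.

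**Figure D3:**
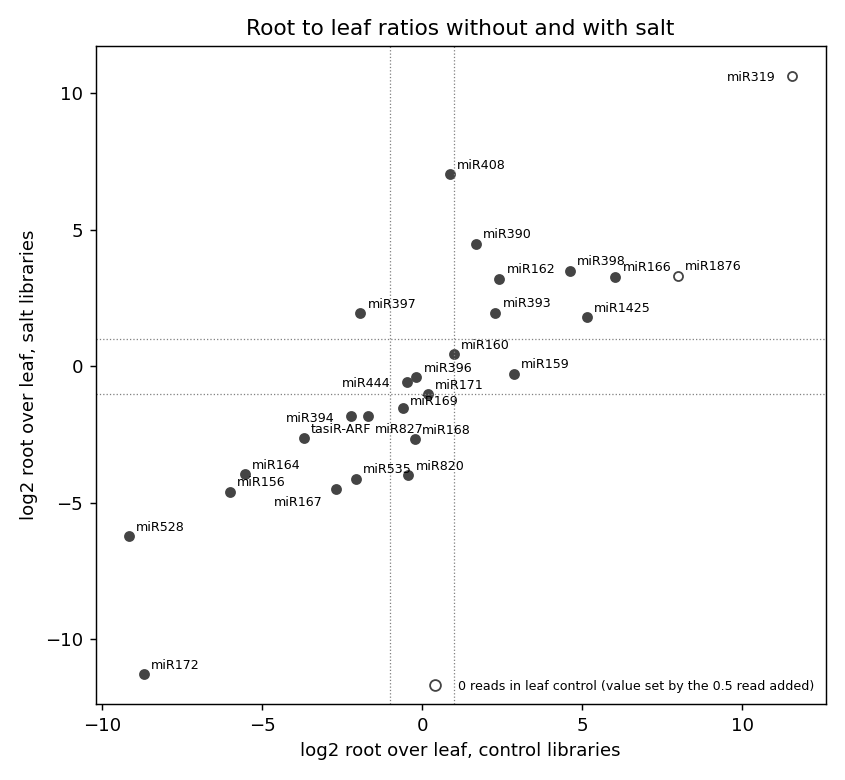
Log2 ratio of root over leaf in the salt libraries (y axis) against the control libraries (x axis), 1 point per family; dotted lines mark 2-fold and open points have 0 reads in leaf control, where the 0.5 read added sets the value. miR319 lies at the upper right and miR172 at the lower left, and miR397 has opposite signs.

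The salt ratios of the tissues were compared for 29 families. None was at least 2-fold higher in 1 tissue and at least 2-fold lower in the other, a count of 0. Root had 1 call, miR820, which was also higher in leaf. The calls already given thus fixed that count, and it says nothing more on whether the tissues agree. The difference of log2 ratios, leaf minus root, was -6.16 (-7.19 to -5.12) for miR408, -3.87 (-4.42 to -3.32) for miR397, 3.56 (3.18 to 3.93) for miR820 and 2.43 (2.42 to 2.45) for miR168. These differences have no interaction test, since each group is 1 library.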

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

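All tests of explanations in this part were chosen after the results were seen. Families that passed the minimum in both tissues were singled out when the counting intervals of their salt ratio excluded 1 in opposite directions in leaf and root and the ratio was beyond 2-fold in a tissue; the difference itself was not tested. The leaf minus root difference of log2 ratios was 2.76 for miR166, 2.43 for miR168, -1.41 for miR156 and -2.80 for miR390. In root, the miR168 ratio was above 1 (1.19 to 1.20) when scaled by listed-family reads. The root interval of miR390 began just above 1, at 1.00 to 1.18, and included 1 with reads of 20 to 24 nt (0.974 to 1.14), reads of 18 to 25 nt (0.961 to 1.13) or median-of-ratios factors (0.926 to 1.09) as the scale, so neither family met the rule under every scale. miR1876, below the minimum in leaf with 91 reads against 0, also had opposite intervals, with a difference of 4.67 (0.654 to 8.68), and its root log2 ratio of -0.17 became 0.14 with listed-family scaling.

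Reads that the family counts leave out also differed between libraries. The miR159 sequence ending at 17 nt had 149059 reads in leaf salt and 13 in leaf control. Reads outside 18 to 30 nt made up 43.2% of root salt, against 39.5% of root control.

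In leaf salt the 17 nt form made up 99.9% of the 17 and 21 nt miR159 reads, against 11.7% in leaf control, 0.494% in root control and 1.09% in root salt. Trimming at TCTG, the bases that the 17 nt form lacks, would deplete that motif late in other reads. Outside the listed families its late frequency relative to the read start was 1.20 times that of leaf control, and the 21 nt miR167, which also ends in TCTG, was kept, with 4.18% at 17 nt; both argue against it, though a longer motif was not tested. Reads of 17 nt made up 2.19% of leaf salt and 0.328% of leaf control, yet in leaf salt the other 25 families with enough reads had a median of 1.13% and at most 21.6% of their 17 to 24 nt reads at 17 to 19 nt, against 99.3% for miR159, which argues against general shortening to these lengths as its whole cause. Shorter products cannot be seen, as the leaf salt file held 3485 reads of 16 nt against 408907 of 17 nt; what shortened miR159 stays open, and salt as a cause rests on 1 library.

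In leaf 21 families were beyond 2-fold and in root 1. With reads of 20 to 24 nt as the scale 22 leaf families were beyond 2-fold, and 19 had their whole counting interval beyond it, which argues against scaling and counting error as its whole cause. Animal or dicot RNA in leaf control would move the grass or rice restricted families by a common factor. Yet 5 of 7 (miR530, which dicots have, left out) had intervals beyond 2-fold of their median ratio. This argues against such RNA as the whole cause for these families, while dilution beside other changes cannot be told apart. miR1318, beyond it from 2 leaf control reads, and miR1432, not beyond it, are the same RNA, so the 7 are not independent. RNA of another plant that adds conserved families cannot be told apart: dicot control sequences stood at 10.7 RPM in leaf control and 0.274 in leaf salt, below the median family level of 37.3. Library preparation cannot be told apart from salt, with a 5' adapter share 3.14 times higher in leaf control and 1 library per state, and plant age, variety and salt itself stay open and untested.

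Animal control sequences had 137 reads in leaf control. At the same rate leaf salt would hold 1115 and it held 2, or 0.179%, which argues against rice sequences that equal animal microRNAs. Of the 5 animal sequences 3 were above 3 reads in leaf control, which reads of another sample in that library would give. The root libraries held 19 and 72 animal reads. There too 3 sequences were above 3 reads, with 9, 5 and 5 in root control and 21, 32 and 17 in root salt. That rule thus does not single out leaf control and cannot decide where the reads came from. No biological explanation was tested.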

How the results depend on the processing

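Tests with reads of 18 to 25 nt, shifted starts, the first 15 nt, thinned libraries and the grass or rice list without miR530 were chosen after seeing the data. Of 96 recomputed counts of called families, 84 were within 1.5 times the main count. Requiring 100 reads in both libraries gave 6 higher and 3 lower of 13 families in leaf, 3 higher and 5 lower of 11 in root control against leaf control, and 4 higher of 23 in root salt against leaf salt, where fewer families were tested. The single higher family of root became 4 when scaled by listed-family reads, 0 with median-of-ratios factors, 2 with 1 mismatch, 3 with the minimum of 10 reads, 0 with the whole interval beyond 2-fold, 0 when scaled to reads of 18 to 25 nt and 2 in thinned libraries. With exact matches the count was 1, but of miR399 (2.02), while miR820 was below the minimum. The main ratios of miR820 and miR399, 2.06 and 1.99, were next to the threshold. miR399 was the family added with 1 mismatch (2.006) and in thinned libraries (2.56). Scaling by listed-family reads added miR169, miR399 and miR1425. No further cause of these counts was tested. Of 987 recomputed ratios of the families that passed the minimum, 616 stayed within the counting interval, 368 left it and 3 of called families reversed: miR159 in leaf, at a log2 ratio of -2.89 with exact matches, which kept 108 and 98 of its reads, and miR171 in root salt against leaf salt, at 0.23 with median-of-ratios factors and 1.19 with shifted starts, where the cause was not tested. Of 310 list medians 3 that were beyond 2-fold reversed. With 100 reads in both libraries the grass or rice restricted list in leaf was at -1.39, with 2 members left, and the copper list in root salt against leaf salt at -6.22, with 1. With the minimum of 10 reads the phosphate list in root control against leaf control was at 0.87, with miR399 added. Beside the shifts given with each comparison, scaling moved the median log2 ratio of the families by more than 0.1 with reads of 20 to 24 nt in leaf (0.14), in root control against leaf control (0.46) and in root salt against leaf salt (0.27), with reads of 18 to 25 nt in these root to leaf pairs (0.27 and 0.14), and with listed-family reads in root control against leaf control (0.63). Scaling to genome-matched reads was not run, as no genome was used here. No paired analysis was possible because each group has 1 library. Depth limits leaf control most, where 3 reads are 1.34 RPM.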

Other observations

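The forms of several families differed by tissue; these were chosen after their values were seen. miR820 was mostly 24 nt long in leaf, 97.1% (96.8 to 97.4) of 22 and 24 nt reads in leaf salt, but 31.8% (29.0 to 34.8) in root salt. miR167 was mostly 22 nt in leaf, 94.7% of 21 and 22 nt reads in leaf salt, against 52.3% in root salt. A 24 nt form of miR168 made up 23.3% of its 21 and 24 nt reads in root salt and 0.170% in leaf salt. The miR166g sequence made up 33.2% of its reads together with the main miR166 form in leaf salt, and 0.0325% in root salt.

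Abundant forms also began away from the listed start. The miR156 form 1 base upstream held 53.0% of the reads of both forms in leaf control and 45.9% in root salt. The miR166 form 2 bases upstream held 29.3% in root salt and 4.79% in leaf salt. The miR397 form 3 bases downstream held 97.9% in leaf control, and its level was 1997 RPM there and 64.9 in leaf salt, so the lower miR397 of leaf salt did not rest on the few reads at the listed start. miR156 is high in juvenile and miR172 in adult shoots; the labels give no plant age.

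Among the most abundant unlisted sequences of 20 to 24 nt, a 22 nt sequence had 112653 reads in root control and 185229 in root salt, against 0 in leaf control and 0.164 RPM in leaf salt. A 21 nt sequence had 1266 RPM in leaf salt and 29.0 in leaf control. Of 6 dicot control sequences, 1 had 24 reads in leaf control and 5 in leaf salt.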
